A study of Mus musculus with 15 samples.

How the data were processed

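The table analysed holds gene expression of 15 RNA-seq libraries of mouse OT-I CD8 T cells, 3 for each of 5 sorted populations, with 23284 entries under gene symbols. Per the labels' protocols, CD8 T cells were mixed with peptide-coated bone marrow dendritic cells, cultured for 14 days, sorted by immunophenotype, and RNA was extracted with the PicoPure kit for Illumina libraries. The submitters' processing notes name TopHat2 2.0.9, an aligner, Cuffdiff 2.1.1, which estimates transcript abundance, and the mouse genome build mm10. The FPKM values in the table are normalized values that the authors deposited, with 1 column per library. The annotation, the settings, any filter and whether strand was used are not given in the sources used here. Libraries were assigned to populations by their labels.

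No read counts were available for these values, and an FPKM value does not carry its depth. For low genes, 28375 ratios between libraries were checked for whole multiples of a single read, and 20.3% lay within 0.05 of a whole number, where chance gives 10%, so whole reads could not be recovered and depth is unknown. FPKM sums ran from 669341 to 781949 per library, and small RNA genes held 4.86% to 17.2% of them. Of all entries, 6039 were at 0 in every library. They included Eef1a1, so a value of 0 can be a failed estimate, and genes at 0 in all libraries of a population are described only as listed at 0. Short transcripts can have inflated FPKM values, since the unit divides by transcript length.

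Values were taken to log2(FPKM + 1) without further scaling, and genes with a group mean of at least 1 FPKM in any population were kept, which left 11242. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on all 15 libraries with population as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within the comparison together with a log2 fold change of at least 1 in size. There were 7 comparisons. The adjusted p of a gene is from limma throughout. An exact permutation test on 3 against 3 libraries cannot give a two-sided p below 0.1. The steps were tested on simulated data for the comparison of the cocktail and IL-2 CD44+CD62L- cells, with 10596 genes: of 50 genes changed 3-fold 41 were called, of 50 changed 8-fold 47 and of 50 changed 20-fold 48, with 1 unchanged gene called. Of 50 genes changed 1.5-fold, which lies under the minimum fold, 46 passed the adjusted p and 0 were called.

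Gene lists were fixed before the data were examined, together with the model, the rule for named genes and the alternatives, except where the text says otherwise. A list needed 3 measured members, and 28 lists were tested in each comparison with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 196 tests. Of these, 94 passed, and 75 passed with an estimated correlation, all of them among the 94. The 9 B cell, 16 dendritic cell and macrophage, 3 NK cell, 5 CD4 T cell and 5 erythroid, platelet and neutrophil markers tested are those that passed the filter. Members were counted as risen or fallen by the criteria above, once with p adjusted over all genes tested and once adjusted over the list alone. The counts were equal in every list and comparison except the ribosomal protein genes in the IL-2 cells against naive cells. Named genes were the 10 highest and 10 lowest changed genes in the comparisons within the cultures and of the cocktail CD44loCD62L+ with naive cells, and the 5 highest and 5 lowest in the others. Each had a mean of at least 10 FPKM in the higher population and no overlap between replicates, and predicted genes, micro, small nucleolar and Cajal body RNAs and antigen receptor segments were left out. From each list discussed, up to 4 members with a mean of at least 5 FPKM in a compared population were named, the 2 with the highest and the 2 with the lowest fold change.

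The distance between populations was the root mean square difference of group means over the genes tested. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-ratio scaling and quantile normalization, a fit to the 6 libraries compared, the replicate number as a block, no variance trend, other fold minimums and leaving out each library in turn. Fits without genes listed at 0 throughout a compared population and without small RNA genes were added after the data were examined. Gene positions are from the GENCODE annotation of GRCm38, the assembly that mm10 names, and are whole gene spans. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.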

Results

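RNA-seq was carried out on mouse OT-I CD8 T cells, which carry a transgenic T cell receptor specific for the ovalbumin peptide SIINFEKL presented by H-2Kb. Cells were stimulated with peptide-coated dendritic cells grown from bone marrow and kept for 14 days either in IL-2, a growth factor of activated T cells, or in a cocktail made up of TWS119, 2-deoxyglucose, IL-21 and IL-7. IL-7 and IL-21 are cytokines of the same receptor family as IL-2, 2-deoxyglucose is a glucose analogue that inhibits glycolysis, and TWS119 inhibits glycogen synthase kinase 3, a negative regulator of beta-catenin. The cultures were sorted by CD44, an adhesion receptor raised on antigen-experienced cells, and CD62L, a homing receptor of naive and central memory T cells. There were 5 populations: CD44+CD62L- cells from IL-2, CD44+CD62L-, CD44+CD62L+ and CD44loCD62L+ cells from the cocktail, and uncultured naive cells. The naive gate is given as CD44-CD62L+ in the design text and as CD44loCD62L+ in the sample labels. Each population had 3 libraries, described as technical replicates, for a total of 15. The p-values of single genes therefore measured only the spread between libraries of a population and not that between mice or cultures. The p-values of gene lists compare the members with the other genes tested, and do not measure the spread between mice or cultures either. The estimated correlation between list members came from the same technical libraries. Values were FPKM, fragment counts scaled by transcript length and library total, and no read counts were given, so sequencing depth was unknown. Between 10006 and 10473 genes reached 1 FPKM in a library, and the median coefficient of variation between replicates was 3.94% to 4.69% for genes of 1 to 10 FPKM, 1.80% to 1.95% for genes of 10 to 100 FPKM and 0.834% to 0.998% above 100 FPKM. Values are mean ± SD in FPKM (n = 3) and log2 fold changes ± SE on the log2(FPKM + 1) scale, which understates the change of low genes.

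Cd44 (chromosome 2, 102811141 to 102901665 of GRCm38), the transcript of a sort marker, was at 23.9 ± 0.773 FPKM in the IL-2 cells, 38.8 ± 0.354 in the cocktail CD44+CD62L- cells, 38.5 ± 0.866 in the cocktail CD44+CD62L+ cells, 31.3 ± 0.591 in the cocktail CD44loCD62L+ cells and 7.24 ± 0.228 in naive cells. The cocktail CD44loCD62L+ cells thus had more Cd44 transcript than naive cells (log2 fold change 1.97 ± 0.0261, limma adjusted p = 1.37e-16) and less than the cocktail CD44+CD62L+ cells, where the difference did not reach the minimum fold (log2 fold change -0.29 ± 0.0261). As CD44 defined the gates, these differences are not independent of the sort.

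**Figure D1:**
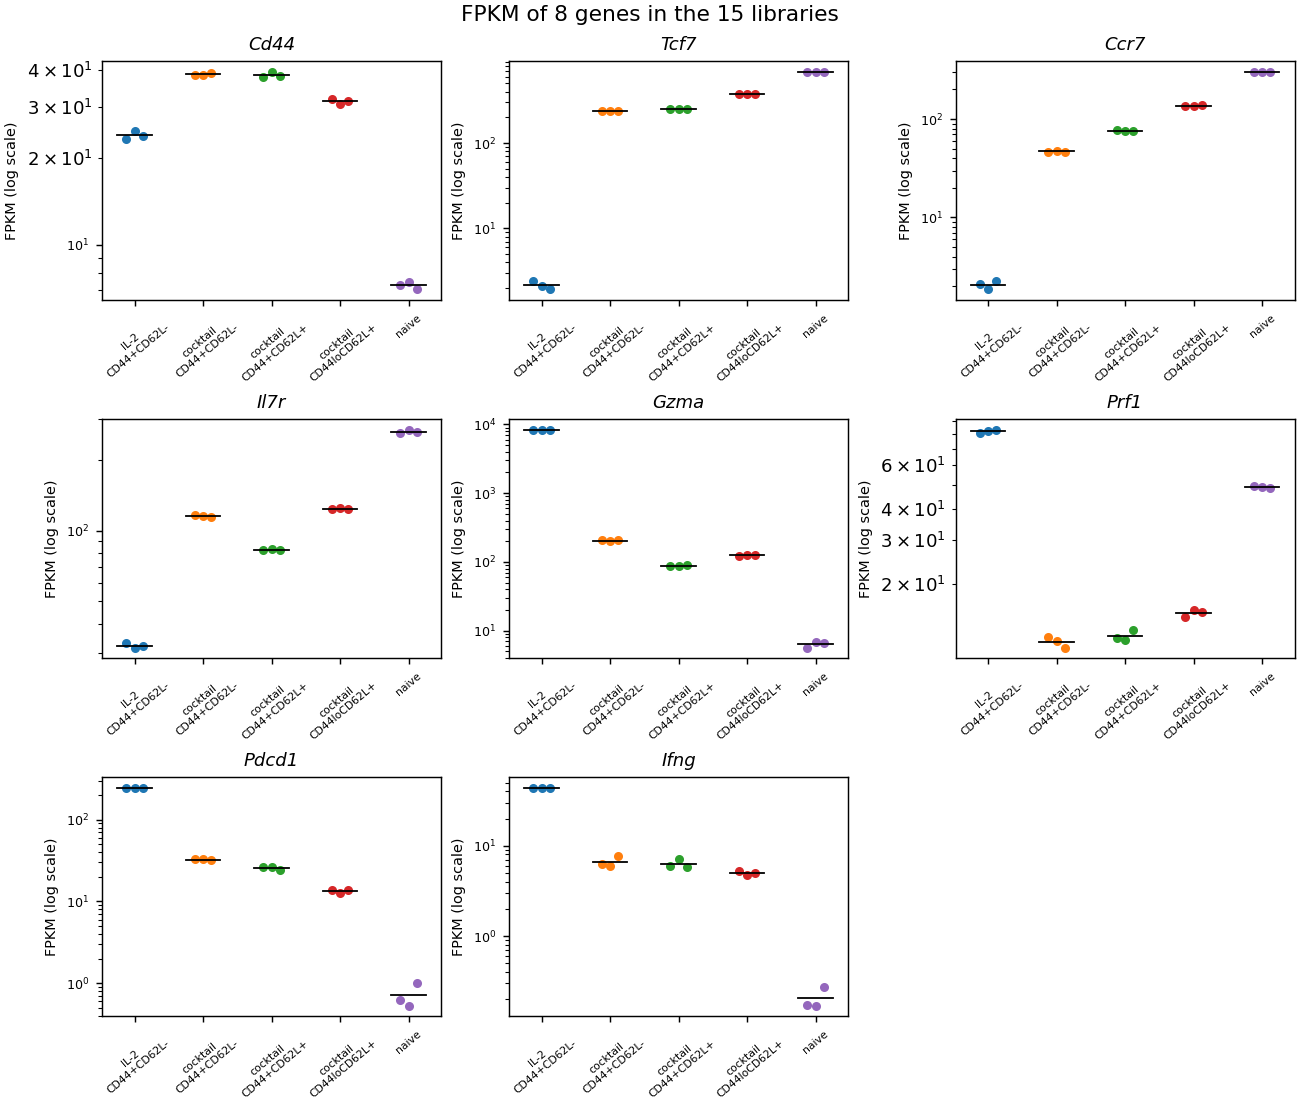
FPKM of 8 genes (Cd44, Tcf7, Ccr7, Il7r, Gzma, Prf1, Pdcd1 and Ifng) in each of the 15 libraries, on a log axis, with the 5 populations along the x axis; points are single libraries and lines are means of 3. Tcf7 lay at 2.16 in the IL-2 cells and 679.9 in naive cells, with the cocktail populations between them.

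The cocktail CD44+CD62L- cells were compared with the IL-2 CD44+CD62L- cells, which had the same surface gate, to measure the difference between the culture conditions. Genes of naive and central memory T cells were higher in the cocktail cells and most cytotoxic effector genes that changed were lower. Tcf7 (chromosome 11, 52252371 to 52283014), a transcription factor of naive and memory T cells, was at 237 ± 2.24 against 2.16 ± 0.257 FPKM, log2 fold change 6.24 ± 0.0394, adjusted p = 4.63e-19. The lymph node homing chemokine receptor gene Ccr7 was at 46.9 ± 0.844 against 2.08 ± 0.209 FPKM, log2 fold change 3.96 ± 0.0351, adjusted p = 9.43e-18, and Il7r, the IL-7 receptor alpha chain, at 116 ± 1.02 against 32.3 ± 0.690 FPKM. Gzma (chromosome 13, 113093825 to 113100981), encoding granzyme A, fell by 5.32 on the log2 scale, 205 ± 4.46 against 8244 ± 42.0 FPKM (SE 0.0422, adjusted p = 3.10e-18). In all, 882 of 11242 genes tested changed, 522 higher and 360 lower in the cocktail cells.

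Of the 24 measured naive and central memory genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 1.34 (camera adjusted p = 6.14e-05). Dapl1 was at 48.5 ± 0.698 against 0.247 ± 0.105 FPKM. Of 16 memory T cell genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 2.31e-04), and Bcl2, an inhibitor of apoptosis, was at 92.9 ± 0.473 against 25.9 ± 0.410 FPKM. Of 34 effector genes 1 rose and 16 fell (1 and 16 adjusted over the list alone, median -0.93, adjusted p = 0.00254). Prf1, encoding perforin, was at 11.7 ± 0.586 against 82.3 ± 1.05 FPKM, and Ifng, encoding interferon gamma, at 6.63 ± 0.919 against 43.2 ± 0.231 FPKM. The member that rose was Gzmb (granzyme B, chromosome 14, 56258838 to 56262260), which was listed at 0, 0 and 0 FPKM in the IL-2 libraries and at 1385, 1371 and 1366 in the cocktail CD44+CD62L- libraries. Eef1a1, a translation factor used by every cell, was listed at 0 in all 15 libraries, so a value of 0 in this table can be a failed estimate and no fold is given for Gzmb. Of 17 inhibitory receptor and exhaustion genes 3 rose and 7 fell (3 and 7 adjusted over the list alone), without a shift of the list (adjusted p = 0.533).

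Of 34 type I interferon response genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.61, adjusted p = 3.13e-05). Gbp2, an interferon-induced GTPase gene, was at 170.0 ± 2.11 against 16.1 ± 0.314 FPKM, and Oas2 lower at 5.10 ± 0.187 against 11.4 ± 0.287 FPKM. Of 19 hypoxia genes 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.93, adjusted p = 1.07e-04), among them the angiogenic factor gene Vegfa at 15.6 ± 0.837 against 1.46 ± 0.201 FPKM. In the same cells, dendritic cell and macrophage markers were also higher: of 16 measured, 7 rose and 0 fell (7 and 0 adjusted over the list alone), including H2-Ab1 at 13.7 ± 1.34 against 0.622 ± 0.0300 FPKM and Lyz2 at 21.3 ± 0.710 against 0.427 ± 0.0584 FPKM. The call of that marker list was lost with an estimated correlation (adjusted p = 0.0153 with the preset correlation, adjusted p = 0.0592 with an estimated correlation).

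The glycolysis list was higher in the cocktail cells (median 0.41, adjusted p = 2.72e-04), where 2 rose and 0 fell of 22 (2 and 0 adjusted over the list alone), with the glucose transporter gene Slc2a3 at 61.9 ± 0.762 against 25.6 ± 0.128 FPKM. The oxidative phosphorylation list was lower (median -0.46, adjusted p = 8.85e-10), where 0 rose and 2 fell of 38 (0 and 2 adjusted over the list alone). Ndufa4 was at 145 ± 5.17 against 355 ± 8.42 FPKM. Cholesterol synthesis genes were lower (median -0.74, adjusted p = 2.09e-06), where 0 rose and 5 fell of 22 (0 and 5 adjusted over the list alone). Idi1 was at 28.9 ± 0.184 against 70.7 ± 1.77 FPKM. Cell cycle genes were lower, with a median of -0.32 (adjusted p = 1.46e-04), where 0 rose and 1 fell of 38 (0 and 1 adjusted over the list alone). No member of the 37 ribosomal protein genes was called, while the list was higher by a median of 0.14 (adjusted p = 3.59e-05, but 0.227 after quantile normalization). Endoplasmic reticulum chaperone genes (0 and 1 of 20 rose and fell, adjusted p = 0.00459) and T cell identity genes (1 and 0 of 18, adjusted p = 0.0482) lost their calls, at adjusted p = 0.0592 and adjusted p = 0.139 with an estimated correlation.

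The remaining lists did not shift as a whole, with 5 and 6 of 23 IL-2 and STAT5 target genes risen and fallen, 5 and 3 of 25 cytokine receptor genes, 3 and 3 of 12 secreted cytokine genes, 3 and 7 of 26 chemokine, adhesion and homing genes, 3 and 5 of 23 immediate early genes, 3 and 0 of 22 apoptotic genes, 4 and 0 of 23 amino acid response genes, 2 and 0 of 7 Wnt and beta-catenin target genes, 0 and 1 of 26 fatty acid oxidation genes and 0 and 1 of 10 heat shock genes, each count being equal when adjusted over the list alone. The risen IL-2 and STAT5 target genes included Gzmb, whose value of 0 in the IL-2 libraries may be a failed estimate. Il2ra, the high-affinity IL-2 receptor chain, was lower in the cocktail cells at 72.6 ± 0.823 against 235 ± 1.07 FPKM, and so was Il10 at 0.0292 ± 0.0291 against 16.7 ± 0.820 FPKM. The cytokine gene Lif was higher at 44.6 ± 0.476 against 0.334 ± 0.0619 FPKM. Markers of other cells rose and fell in 0 and 2 of 9 for B cells, 1 and 1 of 3 for NK cells, 2 and 2 of 5 for CD4 T cells and 3 and 0 of 5 for erythroid cells, platelets and neutrophils, with no list shifted. In the cytokine receptor, secreted cytokine, chemokine, amino acid response, apoptotic and NK cell lists the median and the mean differed in sign.

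Among the genes with the largest changes, Nrn1, encoding neuritin, was at 204 ± 1.18 against 2.67 ± 0.169 FPKM, log2 fold change 5.81 ± 0.0276, adjusted p = 3.32e-20, and the interferon-inducible GTPase gene Iigp1 at 90.1 ± 0.923 against 2.07 ± 0.252 FPKM. Ms4a4c, Serpina3f, Tgm2 and Tnfsf8, the CD30 ligand gene, rose by 4.50, 4.22, 4.20 and 4.07 log2 units. Ifitm1, an interferon-induced membrane protein gene, had the lowest fold change of the named genes, at 57.3 ± 1.19 against 3585 ± 34.4 FPKM, log2 fold change -5.94 ± 0.0790, adjusted p = 4.26e-16. Igj, encoding the immunoglobulin joining chain, Gja5, Wnt10b, Tnfrsf8, the CD30 gene, Esm1 and Sult2b1 had log2 fold changes of -4.67, -4.22, -4.04, -3.94, -3.90 and -3.74, and the ribonuclease P RNA gene Rpph1 one of -4.38. Of the changed genes, 12 were listed at 0 throughout a compared population, and without such genes 871 changed. Members of near-identical families, such as Serpina3f here and Klra5, Lilrb4 and Gp49a in other comparisons, can share reads, so their separate values are uncertain.

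Within the cocktail culture, CD44+CD62L+ cells were compared with CD44+CD62L- cells, which differed in the CD62L gate. Only 13 genes changed, 4 higher and 9 lower in the CD62L+ cells. Penk, encoding proenkephalin, was higher at 25.6 ± 0.724 against 10.3 ± 0.357 FPKM, log2 fold change 1.23 ± 0.0393, adjusted p = 1.82e-10. Gzma was lower at 88.4 ± 1.20 against 205 ± 4.46 FPKM, log2 fold change -1.20 ± 0.0422, adjusted p = 4.14e-10. Ifitm1 (26.3 ± 1.70 against 57.3 ± 1.19 FPKM) and Klra5, a Ly49 receptor gene (7.40 ± 0.477 against 16.7 ± 0.193 FPKM), were also lower. Of the 13 genes, 5 were small RNA genes and 4 were listed at 0 in all libraries of a population, including the small nuclear RNA gene Rnu73b in the CD62L+ cells; 8 genes changed without the small RNA genes and 9 without those listed at 0. Clec12a, the predicted gene Gm156 and the ribonuclease P RNA gene Rpph1, named here after their values were seen, were the other lower genes outside the small RNA genes.

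Smaller shifts ran through whole lists. Cell cycle genes were higher in the CD62L+ cells by a median of 0.28 (adjusted p = 2.63e-15), although of 38 members 0 rose and 0 fell (0 and 0 adjusted over the list alone). The mitotic kinase gene Plk1 was at 86.5 ± 0.937 against 57.6 ± 1.06 FPKM. Naive and central memory genes were higher by a median of 0.17 (adjusted p = 1.18e-06), where 1 rose and 0 fell (1 and 0 adjusted over the list alone). Ccr7 was at 76.2 ± 0.967 against 46.9 ± 0.844 FPKM and Tcf7 at 249 ± 2.41 against 237 ± 2.24 FPKM. Effector genes were lower, with a median of -0.07 (adjusted p = 0.0143), where 0 rose and 1 fell (0 and 1 adjusted over the list alone), the member called being Gzma. After quantile normalization the call of the effector list was lost (adjusted p = 0.130). Immediate early genes were higher (median 0.19, adjusted p = 4.01e-05), and type I interferon response genes (median -0.05, adjusted p = 8.14e-04) and endoplasmic reticulum chaperone genes (median -0.10, adjusted p = 4.12e-05) lower, with no member of these lists called. The lower hypoxia list (median -0.09, adjusted p = 0.00968) was lost at adjusted p = 0.0555 with an estimated correlation. No marker of another cell type was called, and the dendritic cell and macrophage list was not shifted (median -0.22, adjusted p = 0.10).

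The cocktail CD44loCD62L+ cells were compared with the CD44+CD62L+ cells of the same culture, which differed in the CD44 gate. Cell cycle genes fell in the CD44loCD62L+ cells: of 38 measured, 0 rose and 28 fell (0 and 28 adjusted over the list alone), with a median log2 fold change of -1.35 (adjusted p = 1.24e-20). The mitotic kinase gene Plk1 was at 21 ± 0.554 against 86.5 ± 0.937 FPKM, log2 fold change -1.99 ± 0.0251, adjusted p = 1.11e-15, and Cdk1, the kinase that drives entry into mitosis, at 15.7 ± 0.195 against 62.2 ± 1.23 FPKM. Klf2 (chromosome 8, 72319033 to 72321656), a transcription factor of quiescent T cells, was higher at 52.7 ± 0.752 against 17.3 ± 0.357 FPKM, log2 fold change 1.55 ± 0.0182, adjusted p = 5.76e-16, and so was S1pr1, a receptor for exit from lymphoid tissue, at 35.3 ± 0.562 against 14.1 ± 0.118 FPKM. In all, 301 genes changed, 47 higher and 254 lower, 293 without genes listed at 0 in all libraries of a population.

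Of 24 naive and central memory genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.56, adjusted p = 6.73e-11). Klf3 was at 12.7 ± 0.275 against 3.56 ± 0.304 FPKM. Tcf7 (376 ± 2.84 against 249 ± 2.41 FPKM) and Il7r (124 ± 0.257 against 83.0 ± 0.624 FPKM) did not reach the minimum fold. Of 34 type I interferon response genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.24, adjusted p = 9.93e-08), the member called being Ifit3 at 82.7 ± 1.06 against 35.5 ± 0.874 FPKM. Of 19 hypoxia genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.17, adjusted p = 0.00369), the member called being Vegfa. Of 18 T cell identity genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.18, adjusted p = 1.23e-05), the member called being Cd7 at 27.6 ± 0.682 against 9.10 ± 0.677 FPKM. Memory T cell genes (median 0.33, adjusted p = 0.00961), immediate early genes (median 0.27, adjusted p = 0.00194) and ribosomal protein genes (median 0.19, adjusted p = 8.47e-17) were higher as lists. Of their members, 0 and 1 of 16, 0 and 0 of 23 and 0 and 0 of 37 rose and fell, and the memory gene that fell was Xcl1, a chemokine gene, at 80.4 ± 1.76 against 163 ± 4.35 FPKM. The call of the ribosomal protein list was lost after quantile normalization (adjusted p = 0.172).

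Amino acid response and ATF4 target genes were lower in the CD44loCD62L+ cells, with a median of -0.35 (adjusted p = 3.60e-06), where 0 rose and 2 fell of 23 (0 and 2 adjusted over the list alone), namely Slc7a5, an amino acid transporter gene (37.3 ± 0.973 against 77.5 ± 0.840 FPKM), and Psat1, a serine synthesis enzyme gene (40.1 ± 0.601 against 87.0 ± 1.25 FPKM). Cholesterol synthesis genes (median -0.51, adjusted p = 7.63e-07) and oxidative phosphorylation genes (median -0.18, adjusted p = 1.34e-05) were lower with no member called, and endoplasmic reticulum chaperone genes were lower (median -0.35, adjusted p = 2.49e-06) with Sdf2l1 called. The lower heat shock list (median -0.18, adjusted p = 0.00332) was lost at adjusted p = 0.0812 with an estimated correlation. The effector list was not shifted (median -0.12, adjusted p = 0.293) and no member was called. No marker of another cell type was called either. Cd74 was at 10.1 ± 0.302 against 17.2 ± 0.737 FPKM.

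Among the largest changes, Kpna2, an importin gene, fell by 2.04 on the log2 scale (45.9 ± 1.05 against 192 ± 3.06 FPKM), and Aurka, Ccnb1, Prc1, Nusap1, Ccna2, Ccnf and Tuba1c, most of them genes of mitosis, had log2 fold changes of -1.99, -1.98, -1.91, -1.86, -1.84, -1.83 and -1.83. Tcp11l2, Pde2a, a phosphodiesterase gene, Bambi-ps1, Arl5c, Ephx1 and Matk, a kinase gene, rose by 1.75, 1.72, 1.33, 1.28, 1.27 and 1.26 log2 units.

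**Figure D2:**
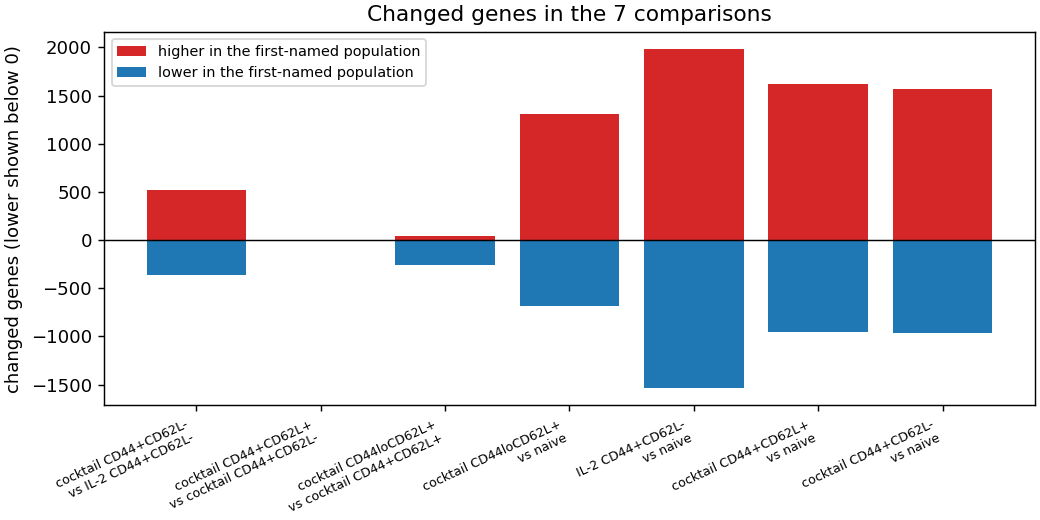
Number of genes changed in each of the 7 comparisons, as bars from 0 for genes higher and genes lower in the first population named. The comparison of CD62L+ with CD62L- cells in the cocktail had 13 changed genes and that of the IL-2 cells with naive cells 3519.

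The cocktail CD44loCD62L+ cells were compared with uncultured naive cells, which have a similar surface phenotype. Cell cycle and effector genes were higher in the cultured cells, and most naive and central memory genes were lower. Of 38 cell cycle genes 33 rose and 0 fell (33 and 0 adjusted over the list alone, median 3.26, adjusted p = 3.89e-15). Ube2c, a mitotic ubiquitin-conjugating enzyme gene, was at 82.6 ± 2.77 against 1.28 ± 0.254 FPKM, log2 fold change 5.20 ± 0.0571, adjusted p = 1.84e-17. Of 34 effector genes 23 rose and 1 fell (23 and 1 adjusted over the list alone, median 2.33, adjusted p = 1.03e-08). Gzmb was at 896 ± 3.87 against 3.91 ± 0.0604 FPKM, log2 fold change 7.52 ± 0.00973, adjusted p = 7.62e-27. In all, 1993 genes changed, 1306 higher and 687 lower (65.5% higher), and after quantile normalization the split was 1094 and 880 (55.4% higher).

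Of 24 naive and central memory genes 2 rose and 16 fell (2 and 16 adjusted over the list alone, median -1.35, adjusted p = 1.77e-05). Among those that fell, Il6ra, the IL-6 receptor gene, was at 0.351 ± 0.0464 against 69.5 ± 0.967 FPKM and Klf3 at 12.7 ± 0.275 against 87.4 ± 1.64 FPKM, while Bcl2 rose (105 ± 0.255 against 28.0 ± 0.662 FPKM) and Tcf7 did not reach the minimum fold (376 ± 2.84 against 679.9 ± 2.48 FPKM). Within the effector list Prf1 fell (15.3 ± 0.474 against 48.9 ± 0.428 FPKM) and Bhlhe40, a transcription factor gene of activated T cells, rose (66.7 ± 0.368 against 0.458 ± 0.102 FPKM). Of 17 inhibitory receptor and exhaustion genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00147, but adjusted p = 0.0545 with an estimated correlation). Ctla4 was at 129.9 ± 0.70 against 0.817 ± 0.148 FPKM, Lag3 at 95.9 ± 1.16 against 0.434 ± 0.127 FPKM and Tox lower at 5.61 ± 0.00624 against 20.6 ± 0.718 FPKM. Of 23 IL-2 and STAT5 target genes 14 rose and 3 fell (14 and 3 adjusted over the list alone, median 1.38, adjusted p = 0.00147). Il2ra was at 46.6 ± 0.874 against 0.511 ± 0.0472 FPKM. Wnt and beta-catenin target genes were not shifted as a list (1 and 4 of 7 rose and fell, adjusted p = 0.175), while Axin2, a feedback target of beta-catenin, was lower at 2.22 ± 0.165 against 11.1 ± 0.208 FPKM.

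Of 22 glycolysis genes 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 2.15, adjusted p = 2.97e-08). Slc16a3, a lactate transporter gene, was at 75.7 ± 1.5 against 0.799 ± 0.105 FPKM. Of 34 type I interferon response genes 21 rose and 0 fell (21 and 0 adjusted over the list alone, median 1.16, adjusted p = 5.34e-10). Ly6a was at 1227 ± 8.52 against 84.3 ± 1.45 FPKM. Hypoxia genes (13 rose and 0 fell of 19, 13 and 0 adjusted over the list alone, adjusted p = 2.25e-06), cholesterol synthesis genes (9 rose and 0 fell of 22, 9 and 0 adjusted over the list alone, adjusted p = 1.42e-04) and amino acid response genes (8 rose and 0 fell of 23, 8 and 0 adjusted over the list alone, adjusted p = 7.61e-04) were higher. Vegfa was at 31.0 ± 0.574 against 0.121 ± 0.0344 FPKM and Asns, encoding asparagine synthetase, at 20.9 ± 0.599 against 0.113 ± 0.0116 FPKM. Oxidative phosphorylation genes were higher by a median of 0.25 (adjusted p = 0.00276) with 0 and 1 of 38 risen and fallen. Of 12 secreted cytokine genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.00600, but adjusted p = 0.0831 with an estimated correlation). T cell identity genes were lower (median -0.49, adjusted p = 0.00126), where 0 rose and 4 fell of 18 (0 and 4 adjusted over the list alone). Cd5 was at 54.3 ± 1.40 against 130.2 ± 2.24 FPKM. Ribosomal protein genes were lower, with a median of -0.19 (adjusted p = 0.00462, but adjusted p = 0.139 with an estimated correlation) with no member called. The call was also lost after quantile normalization (adjusted p = 0.652).

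Markers of B cells fell with the naive genes: of 9 measured, 0 rose and 8 fell (0 and 8 adjusted over the list alone, adjusted p = 0.00276). Cd79b was at 2.74 ± 0.198 against 22.6 ± 0.144 FPKM. Of 5 erythroid, platelet and neutrophil markers 0 rose and 4 fell (0 and 4 adjusted over the list alone), without a shift of the list (adjusted p = 0.152). Those that fell included S100a8 (0.744 ± 0.143 against 12.7 ± 1.34 FPKM) and S100a9 (0.230 ± 0.0584 against 14.2 ± 1.35 FPKM). Of 16 dendritic cell and macrophage markers 0 rose and 3 fell (0 and 3 adjusted over the list alone), without a shift of the list (adjusted p = 0.592). H2-Aa, a major histocompatibility gene, fell (0.805 ± 0.204 against 21.8 ± 1.81 FPKM). Cst3 (110.3 ± 2.94 against 64.2 ± 1.72 FPKM) and Lyz2 (11.5 ± 0.174 against 8.22 ± 0.661 FPKM) were not called. The NK cell and CD4 T cell marker lists are not set out here. Il2ra, which is on the CD4 T cell list, rose (46.6 ± 0.874 against 0.511 ± 0.0472 FPKM). Small RNA genes held 11.6% to 17.2% of the FPKM sum in the naive libraries and 4.86% to 10.6% in the cultured ones. The highest genes included Nrn1 (277 ± 2.94 against 0.437 ± 0.0413 FPKM, log2 fold change 7.60 ± 0.0276, adjusted p = 3.18e-22), the metallothionein genes Mt1 (161 ± 1.33 against 0.275 ± 0.216 FPKM) and Mt2 (6.61 log2 units), AA467197 (6.97), Serpina3g (6.14), Lilrb4 (6.01) and Gp49a (5.96). The lowest included Dtx1, a regulator of Notch signalling (0.488 ± 0.0485 against 94.6 ± 2.1 FPKM, log2 fold change -6.01 ± 0.0399, adjusted p = 1.23e-19), and Ccr9, a gut homing chemokine receptor gene (0.0849 ± 0.00712 against 61.0 ± 0.215 FPKM). Igfbp4, Fam101b, Atp1b1, Itgae, Slc16a5, Rcn3 and Ggt1 followed, with log2 fold changes of -5.47, -5.34, -5.25, -4.83, -4.70, -4.38 and -4.13. Of the changed genes, 46 were listed at 0 throughout a population, and 1948 changed without them.

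The IL-2 cells were compared with naive cells as the uncultured reference. Cytotoxic and proliferation genes were far higher in the IL-2 cells and naive genes far lower. Gzma was at 8244 ± 42.0 against 6.38 ± 0.608 FPKM, log2 fold change 10.13 ± 0.0422, adjusted p = 7.21e-22, Gzmc (chromosome 14, 56231441 to 56234656) at 662 ± 3.95 against 0.252 ± 0.0562 FPKM and Ifitm1 (chromosome 7, 140967221 to 140969825) at 3585 ± 34.4 against 0.887 ± 0.271 FPKM. Tcf7 was at 2.16 ± 0.257 against 679.9 ± 2.48 FPKM, log2 fold change -7.75 ± 0.0394, adjusted p = 4.09e-21, and Dapl1 at 0.247 ± 0.105 against 407 ± 7.50 FPKM. In all, 3519 genes changed, 1981 higher and 1538 lower, 3434 without the genes listed at 0 in all libraries of a population. Of all changed genes 56.3% were higher, and after quantile normalization the majority turned, with 1638 higher and 1746 lower (48.4% higher).

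All 38 measured cell cycle genes rose (38 adjusted over the list alone; median 4.63, adjusted p = 1.67e-13). Birc5, encoding survivin, was at 250.5 ± 4.41 against 1.85 ± 0.313 FPKM. Of 34 effector genes 25 rose and 1 fell (25 and 1 adjusted over the list alone, median 3.81, adjusted p = 1.54e-07), the member that fell being Gzmb, listed at 0, 0 and 0 FPKM in the IL-2 libraries and at 3.96, 3.92 and 3.84 in the naive libraries. As the value of 0 may be a failed estimate, the fall of Gzmb is uncertain. No list test was repeated without Gzmb. Of 24 naive and central memory genes 0 rose and 21 fell (0 and 21 adjusted over the list alone, median -3.71, adjusted p = 2.01e-07). Of 17 inhibitory receptor and exhaustion genes 11 rose and 2 fell (11 and 2 adjusted over the list alone, adjusted p = 0.0133, but adjusted p = 0.119 with an estimated correlation). Pdcd1, encoding PD-1, was at 242 ± 0.425 against 0.719 ± 0.246 FPKM. Of 22 cholesterol synthesis genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 1.81, adjusted p = 7.70e-07). Sqle was at 47.1 ± 0.659 against 3.09 ± 0.0341 FPKM. Oxidative phosphorylation genes (14 rose and 0 fell of 38, 14 and 0 adjusted over the list alone, adjusted p = 1.01e-08), glycolysis genes (15 rose and 0 fell of 22, 15 and 0 adjusted over the list alone, adjusted p = 1.29e-05) and amino acid response genes (12 rose and 1 fell of 23, 12 and 1 adjusted over the list alone, adjusted p = 0.00171) were higher. Secreted cytokine genes (5 and 1 of 12 rose and fell, adjusted p = 0.00931) and endoplasmic reticulum chaperone genes (10 and 1 of 20, adjusted p = 0.00891) lost their calls at adjusted p = 0.0969 and adjusted p = 0.0791 with an estimated correlation.

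Type I interferon response genes were not shifted as a list (adjusted p = 0.218). Of them, 9 rose and 3 fell of 34 (9 and 3 adjusted over the list alone), Mx1 being higher (119 ± 1.5 against 7.61 ± 0.220 FPKM) and Gbp2 lower (16.1 ± 0.314 against 83.4 ± 1.01 FPKM). T cell identity genes were lower (median -0.81, adjusted p = 2.19e-04), where 0 rose and 7 fell of 18 (0 and 7 adjusted over the list alone). Ribosomal protein genes were lower, with a median of -0.51 (adjusted p = 1.01e-08), where 0 rose and 1 fell of 37 (0 and 2 adjusted over the list alone). Rps16 was at 1841 ± 7.00 against 4036 ± 19.6 FPKM. That call was lost after quantile normalization (adjusted p = 0.398). Of 9 B cell markers 1 rose and 7 fell (1 and 7 adjusted over the list alone, adjusted p = 0.0240, but adjusted p = 0.0608 with an estimated correlation and 0.572 with a filter of 5 FPKM). Cd79a was at 0.0406 ± 0.0177 against 9.35 ± 0.408 FPKM and Igj, the member that rose, at 26.0 ± 0.472 against 5.26 ± 0.216 FPKM. Of 16 dendritic cell and macrophage markers 0 rose and 9 fell (0 and 9 adjusted over the list alone, adjusted p = 0.0766). Cd74 was at 0.559 ± 0.188 against 57.3 ± 0.609 FPKM. The neutrophil markers S100a8 (0.0611 ± 0.106 against 12.7 ± 1.34 FPKM) and S100a9 (0.0398 ± 0.0690 against 14.2 ± 1.35 FPKM) fell. The NK cell marker Klre1 rose (8.95 ± 0.246 against 1.30 ± 0.166 FPKM). Of the CD4 T cell markers, Il2ra and Zbtb7b rose by 7.29 and 3.70 log2 units. Cd40lg, on the same list, fell (0.413 ± 0.0736 against 7.80 ± 0.832 FPKM). The list tests for these markers are not set out here. S100a4, a calcium-binding protein gene, was 8.58 log2 units higher and Mt1 was at 455 ± 8.23 against 0.275 ± 0.216 FPKM, and Igfbp4 and Nsg2 had log2 fold changes of -6.94 and -6.63.

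The cocktail CD44+CD62L+ cells were also set against naive cells. Gzmb was at 1153 ± 4.17 against 3.91 ± 0.0604 FPKM, log2 fold change 7.88 ± 0.00973, adjusted p = 4.78e-27, and Nrn1 (chromosome 13, 36725361 to 36735131) was at 235 ± 0.943 against 0.437 ± 0.0413 FPKM. Dtx1 (chromosome 5, 120680202 to 120711927) was at 0.230 ± 0.0263 against 94.6 ± 2.1 FPKM, log2 fold change -6.28 ± 0.0399, adjusted p = 4.42e-20, and Ccr9 (chromosome 9, 123678439 to 123784330) at 0.0484 ± 0.0120 against 61.0 ± 0.215 FPKM. All 38 cell cycle genes rose (38 adjusted over the list alone, median 4.79, adjusted p = 3.89e-15). In all, 2564 genes changed, 1615 higher and 949 lower (63.0% higher), and 2518 changed without genes listed at 0 in a whole population. After quantile normalization, which put the median log2 fold change of all genes at -0.11, the split was 1345 and 1225 (52.3% higher). Of 34 effector genes 23 rose and 1 fell (23 and 1 adjusted over the list alone, median 2.65, adjusted p = 2.49e-07), the member that fell being Prf1 at 12.3 ± 0.618 against 48.9 ± 0.428 FPKM. Of 24 naive and central memory genes 1 rose and 20 fell (1 and 20 adjusted over the list alone, median -2.03, adjusted p = 4.87e-06). Il6ra was at 0.0467 ± 0.00554 against 69.5 ± 0.967 FPKM and Bcl2, the member that rose, at 82.4 ± 1.08 against 28.0 ± 0.662 FPKM.

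Of 22 glycolysis genes 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 2.02, adjusted p = 1.38e-07). Tpi1, a glycolytic isomerase gene, was at 774 ± 1.75 against 28.9 ± 0.355 FPKM. Type I interferon response genes (15 rose and 1 fell of 34, 15 and 1 adjusted over the list alone, adjusted p = 2.49e-06), hypoxia genes (12 rose and 0 fell of 19, 12 and 0 adjusted over the list alone, adjusted p = 1.91e-04), cholesterol synthesis genes (14 rose and 0 fell of 22, 14 and 0 adjusted over the list alone, adjusted p = 4.87e-06), amino acid response genes (11 rose and 0 fell of 23, 11 and 0 adjusted over the list alone, adjusted p = 4.12e-05), oxidative phosphorylation genes (2 rose and 1 fell of 38, 2 and 1 adjusted over the list alone, adjusted p = 5.97e-06) and IL-2 and STAT5 target genes (13 rose and 4 fell of 23, 13 and 4 adjusted over the list alone, adjusted p = 0.00965) were higher. Ly6a was at 1501 ± 11.6 against 84.3 ± 1.45 FPKM, Bnip3 at 92.4 ± 1.72 against 2.81 ± 0.492 FPKM and Il2ra at 68.3 ± 1.46 against 0.511 ± 0.0472 FPKM. Inhibitory receptor genes (11 and 2 of 17 rose and fell, adjusted p = 0.00440), secreted cytokine genes (7 and 1 of 12, adjusted p = 0.00653) and endoplasmic reticulum chaperone genes (2 and 1 of 20, adjusted p = 0.0378) lost their calls at adjusted p = 0.0800, adjusted p = 0.0855 and adjusted p = 0.139 with an estimated correlation. The chaperone call was also lost after quantile normalization (adjusted p = 0.0603). T cell identity genes (0 rose and 4 fell of 18, 0 and 4 adjusted over the list alone, adjusted p = 7.96e-04) and ribosomal protein genes (median -0.39, adjusted p = 9.56e-08, with no member called) were lower. The ribosomal protein call was lost after quantile normalization (adjusted p = 0.826). B cell markers were lower too: 0 rose and 8 fell of 9 (0 and 8 adjusted over the list alone, adjusted p = 0.00198, but 0.0516 with a filter of 5 FPKM). Of 5 erythroid, platelet and neutrophil markers 0 rose and 4 fell (0 and 4 adjusted over the list alone), without a shift of the list (adjusted p = 0.175). S100a9 was at 1.18 ± 0.647 against 14.2 ± 1.35 FPKM. Of 16 dendritic cell and macrophage markers 1 rose and 3 fell (1 and 3 adjusted over the list alone), also without a shift (adjusted p = 0.438). Cst3 (141 ± 1.82 against 64.2 ± 1.72 FPKM) rose. H2-Aa (1.10 ± 0.108 against 21.8 ± 1.81 FPKM) and H2-Eb1 (0.937 ± 0.111 against 10.3 ± 0.464 FPKM) fell. The NK cell and CD4 T cell marker lists are not set out here, and Il2ra, higher as given above, is on the CD4 T cell list. Mt1, Mt2 and AA467197 were 7.42, 7.21 and 7.09 log2 units higher. Il6ra and Fam101b had log2 fold changes of -6.07 and -5.80, with Atp1b1 at -5.49.

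The last comparison set the cocktail CD44+CD62L- cells against naive cells. Gzmb was at 1374 ± 9.97 against 3.91 ± 0.0604 FPKM, log2 fold change 8.13 ± 0.00973, adjusted p = 4.25e-27, and Nrn1 was at 204 ± 1.18 against 0.437 ± 0.0413 FPKM. Dtx1 was at 0.239 ± 0.0650 against 94.6 ± 2.1 FPKM, log2 fold change -6.27 ± 0.0399, adjusted p = 4.83e-20, and Ccr9 at 0.0157 ± 0.00787 against 61.0 ± 0.215 FPKM. All 38 cell cycle genes rose (38 adjusted over the list alone, median 4.47, adjusted p = 5.50e-15). In all, 2530 genes changed, 1564 higher and 966 lower (61.8% higher), and 2473 changed without genes listed at 0 in a whole population. After quantile normalization, which put the median log2 fold change of all genes at -0.11, the split was 1331 and 1227 (52.0% higher). Of 34 effector genes 23 rose and 1 fell (23 and 1 adjusted over the list alone, median 2.63, adjusted p = 1.24e-07), the member that fell being Prf1 at 11.7 ± 0.586 against 48.9 ± 0.428 FPKM. Of 24 naive and central memory genes 1 rose and 20 fell (1 and 20 adjusted over the list alone, median -2.34, adjusted p = 1.26e-06). Il6ra was at 0.0411 ± 0.0272 against 69.5 ± 0.967 FPKM and Bcl2, the member that rose, at 92.9 ± 0.473 against 28.0 ± 0.662 FPKM.

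Of 22 glycolysis genes 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 2.08, adjusted p = 1.54e-07). Tpi1, a glycolytic isomerase gene, was at 789 ± 7.24 against 28.9 ± 0.355 FPKM. Type I interferon response genes (17 rose and 1 fell of 34, 17 and 1 adjusted over the list alone, adjusted p = 2.83e-07), hypoxia genes (12 rose and 0 fell of 19, 12 and 0 adjusted over the list alone, adjusted p = 1.07e-04), cholesterol synthesis genes (13 rose and 0 fell of 22, 13 and 0 adjusted over the list alone, adjusted p = 4.87e-06), amino acid response genes (11 rose and 0 fell of 23, 11 and 0 adjusted over the list alone, adjusted p = 4.98e-05), oxidative phosphorylation genes (1 rose and 1 fell of 38, 1 and 1 adjusted over the list alone, adjusted p = 4.87e-06) and IL-2 and STAT5 target genes (13 rose and 4 fell of 23, 13 and 4 adjusted over the list alone, adjusted p = 0.0181) were higher. Ly6a was at 1692 ± 4.98 against 84.3 ± 1.45 FPKM, Bnip3 at 99.3 ± 1.32 against 2.81 ± 0.492 FPKM and Il2ra at 72.6 ± 0.823 against 0.511 ± 0.0472 FPKM. Inhibitory receptor genes (11 and 2 of 17 rose and fell, adjusted p = 0.00514), secreted cytokine genes (8 and 0 of 12, adjusted p = 0.00600) and endoplasmic reticulum chaperone genes (3 and 1 of 20, adjusted p = 0.0162) lost their calls at adjusted p = 0.0831, adjusted p = 0.0831 and adjusted p = 0.0974 with an estimated correlation. Immediate early genes (3 and 11 of 23, adjusted p = 0.0414) likewise lost their call at adjusted p = 0.0667 with an estimated correlation. T cell identity genes (0 rose and 5 fell of 18, 0 and 5 adjusted over the list alone, adjusted p = 0.00126) and ribosomal protein genes (median -0.37, adjusted p = 2.01e-07, with no member called) were lower. The ribosomal protein call was lost after quantile normalization (adjusted p = 0.826). B cell markers were lower too: 0 rose and 8 fell of 9 (0 and 8 adjusted over the list alone, adjusted p = 0.00176, but 0.0505 with a filter of 5 FPKM). Of 5 erythroid, platelet and neutrophil markers 1 rose and 4 fell (1 and 4 adjusted over the list alone), without a shift of the list (adjusted p = 0.206). S100a9 was at 1.22 ± 0.341 against 14.2 ± 1.35 FPKM. Of 16 dendritic cell and macrophage markers 2 rose and 3 fell (2 and 3 adjusted over the list alone), also without a shift (adjusted p = 0.742). Cst3 (146 ± 2.28 against 64.2 ± 1.72 FPKM) and Lyz2 (21.3 ± 0.710 against 8.22 ± 0.661 FPKM) rose. H2-Aa (1.31 ± 0.134 against 21.8 ± 1.81 FPKM) and H2-Eb1 (0.764 ± 0.122 against 10.3 ± 0.464 FPKM) fell. The NK cell and CD4 T cell marker lists are not set out here, and Il2ra, higher as given above, is on the CD4 T cell list. Mt1, Mt2 and AA467197 were 7.35, 7.15 and 7.38 log2 units higher. Il6ra and Fam101b had log2 fold changes of -6.08 and -5.83.

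Over the 11242 genes tested, the cocktail CD44loCD62L+ cells lay closest to naive cells and the IL-2 cells farthest. The root mean square difference between group means in log2(FPKM + 1) was 1.06 (single pairs of libraries 1.10 to 1.16, Pearson r 0.867 across genes) for the cocktail CD44loCD62L+ cells, 1.19 (single pairs of libraries 1.25 to 1.29, Pearson r 0.832 across genes) for the cocktail CD44+CD62L- cells, 1.20 (single pairs of libraries 1.24 to 1.29, Pearson r 0.830 across genes) for the cocktail CD44+CD62L+ cells and 1.38 (single pairs of libraries 1.41 to 1.46, Pearson r 0.784 across genes) for the IL-2 cells. The differences of 1.19 and 1.20 had overlapping ranges, and libraries of a single population differed by 0.39 to 0.57. Genes are not independent replicates, so no test is given. All 4 cultured populations were farther from naive cells than from each other, the largest difference among them being 0.91 between the cocktail CD44loCD62L+ and the IL-2 cells.

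The 4 cultured populations shared 1448 changes against naive cells, 924 genes higher in all 4 and 524 lower in all 4, of 4219 genes changed in at least 1. Mt1 and the cell cycle gene Birc5 were among the genes higher in all 4, and Dtx1 and Il6ra among those lower. After quantile normalization, changes against naive shared by the 4 cultured populations were 758 higher and 667 lower. Independent lists of these sizes would share 4.60 and 0.682 genes, but these lists were not independent. All 4 populations were stimulated and cultured for 14 days, 3 of them in the cocktail, and the cocktail CD44+CD62L+ and CD44+CD62L- cells differed in only 13 genes. A larger overlap than that of independent lists therefore follows from the design and is not evidence by itself. In 50 simulations of unchanged groups against the same naive libraries, 0 genes were shared. Those groups were centred on the observed naive means with the spread between replicates, so the 0 does not measure what shared controls add. The 3 naive libraries are too few to be split, so part of the excess can come from the shared controls.

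**Figure D3:**
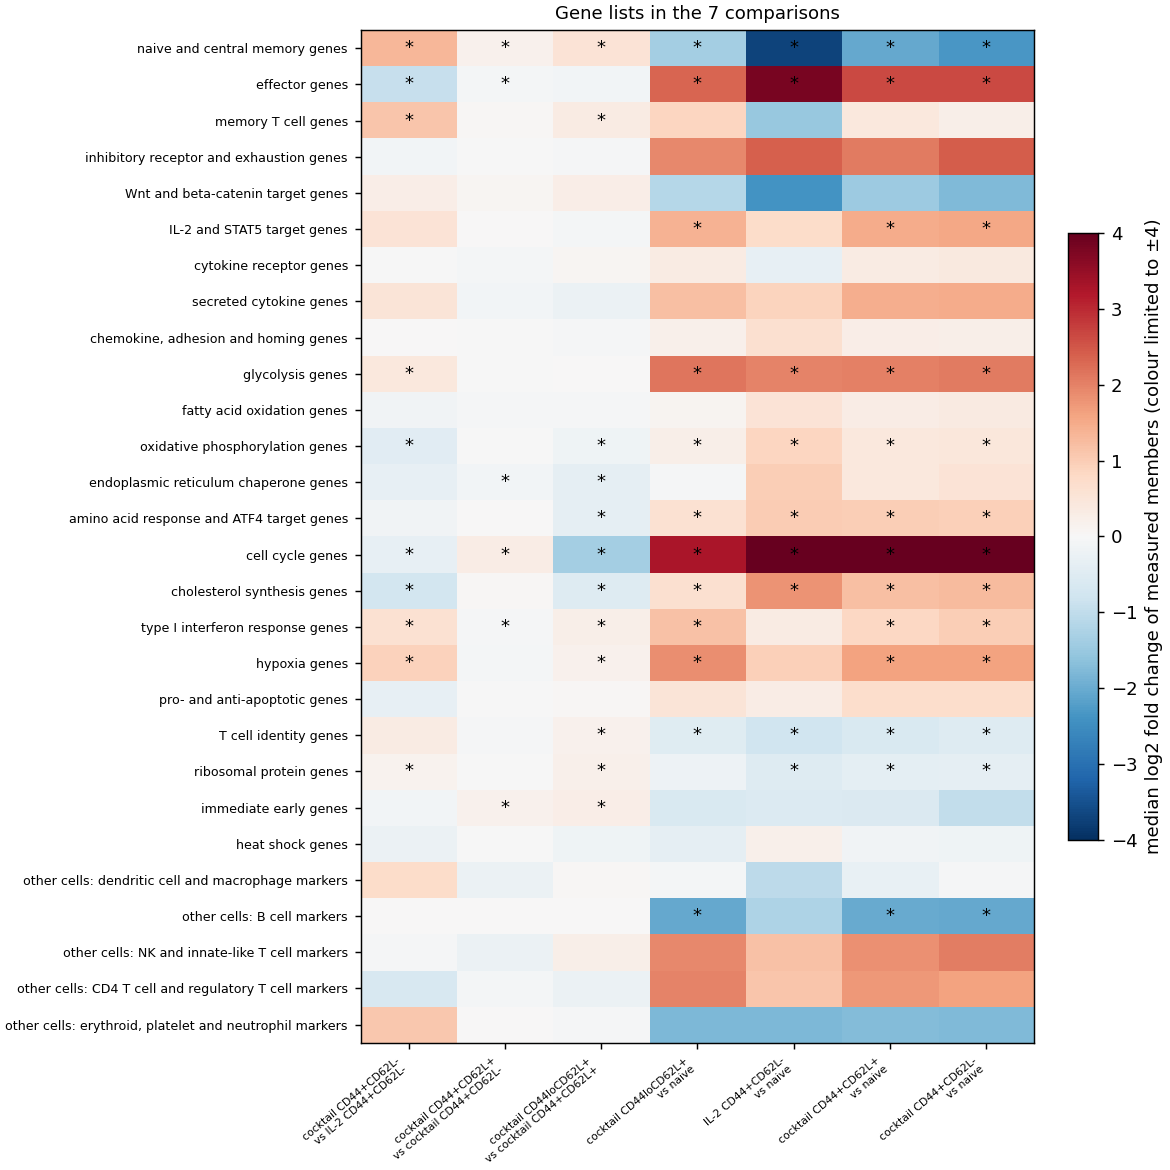
Median log2 fold change of each gene list (y axis) in the 7 comparisons (x axis), as a colour scale, with an asterisk where the list test had an adjusted p under 0.05 with both the preset and an estimated correlation. The cell cycle list was at 4.79 in the cocktail CD44+CD62L+ cells against naive cells and at -1.35 in the cocktail CD44loCD62L+ against the CD44+CD62L+ cells.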

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

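All tests in this part except the one on scaling between libraries were chosen only after the result was seen.

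A set of 12 genes changed in opposite directions against naive cells in the IL-2 cells and in the cocktail CD44+CD62L- cells, although both populations had the same surface gate. They stand out because they lay on opposite sides of the uncultured reference in the culture conditions. All 12 were also called between the cocktail and IL-2 cells by limma, but opposite calls against the same naive libraries fix the direction and minimum size of that difference, so these calls are not separate evidence. Abcb9 and Igj were higher in the IL-2 cells and lower in the cocktail cells. Enpp5, Gbp2, Gm14446, Gzmb, Iigp1, Lyz2, Ms4a4c, Samd3, Tnfsf8 and Vwa5a were the reverse. Iigp1 was at 2.07 ± 0.252 FPKM in the IL-2 cells, 90.1 ± 0.923 in the cocktail CD44+CD62L- cells and 9.83 ± 0.298 in naive cells. Ms4a4c was at 4.53 ± 0.260 FPKM in the IL-2 cells, 124 ± 0.403 in the cocktail CD44+CD62L- cells and 22.9 ± 0.789 in naive cells. Tnfsf8 was at 3.63 ± 0.386 FPKM in the IL-2 cells, 76.7 ± 0.349 in the cocktail CD44+CD62L- cells and 27.8 ± 0.211 in naive cells. Igj was at 26.0 ± 0.472 FPKM in the IL-2 cells, 0.0566 ± 0.0490 in the cocktail CD44+CD62L- cells and 5.26 ± 0.216 in naive cells. Gzmb is in the set only because it was listed at 0 in the IL-2 libraries.

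Scaling between libraries does not account for the pattern as a whole, since 10 of the 12 genes stayed opposite after quantile normalization, which moved the share of higher calls elsewhere, and 12 after median-ratio scaling. RNA from other cells stays open, because 2 of the 12, Lyz2 and Igj, are on a list of markers of other cells. The lists are also short, and the sort on CD44 and CD62L would not by itself remove such cells. Igj, however, was the B cell marker that rose in the IL-2 cells against naive cells, while Cd79a and Cd79b fell there. Cd79a was at 0.0406 ± 0.0177 against 9.35 ± 0.408 FPKM, so Igj does not point to B cells as a source. An effect of the cocktail culture is a candidate explanation, as all 12 had the same sign against naive cells in the 3 cocktail populations, but these populations all came from culture in the cocktail and shared the naive libraries. The set is a hypothesis for follow-up, found and tested on the same libraries.

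Gzmb, listed at 0 in the 3 IL-2 libraries, may be a failed estimate or a true absence. Of 20 genes that every cell uses, 1, Eef1a1, was listed at 0 in all 15 libraries, but those 20 were chosen when that value of Eef1a1 was already known, so the count does not decide. Of 8 other granzyme genes, 7 were called higher in the IL-2 cells than in the cocktail CD44+CD62L- cells, which argues against a general loss of granzyme transcripts but leaves a loss of Gzmb alone untested. The explanations cannot be told apart without the reads.

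The dendritic cell genes H2-Ab1, Cd74 and Lyz2 were above the IL-2 level in the cocktail populations, at 13.7 ± 1.34, 12.5 ± 0.104 and 21.3 ± 0.710 FPKM in the CD44+CD62L- cells against 0.622 ± 0.0300, 0.559 ± 0.188 and 0.427 ± 0.0584 in the IL-2 cells. The same other cells as in the naive libraries do not account for H2-Ab1. The ratio of H2-Aa to H2-Ab1 averaged 0.0666 over the 9 cocktail libraries (0.0325 to 0.118). In the naive libraries it lay between 1.41 and 1.48. This ratio does not bear on Lyz2 and does not test Cd74 directly. Dendritic cells left from the stimulation stay a candidate source. Of the 16 markers tested, 7 were called higher in the cocktail CD44+CD62L- than in the IL-2 cells. This leaves that source open, since the sort on CD44 and CD62L would not by itself remove dendritic cells. The low ratio of H2-Aa to H2-Ab1 argues against a source of H2-Ab1 in which these genes are at similar levels. Whether that holds for dendritic cells was not tested, as no dendritic cell profile was measured. Expression by the T cells themselves was not tested.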

How the results depend on the processing

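The fits without small RNA genes and without genes listed at 0 were chosen only after the data were seen. Counts of changed genes are given in the order cocktail against IL-2 CD44+CD62L- cells, cocktail CD44+CD62L+ against CD44+CD62L-, cocktail CD44loCD62L+ against CD44+CD62L+, and then cocktail CD44loCD62L+, IL-2, cocktail CD44+CD62L+ and cocktail CD44+CD62L- cells against naive cells. They were 882, 13, 301, 1993, 3519, 2564 and 2530 as reported. They stayed within 1.5 times of these values without a filter, with a filter of 5 FPKM, under both scalings, with the 6 libraries compared, without the variance trend and without genes listed at 0. With log2(FPKM + 5) they were 379, 7, 178, 1014, 2038, 1412 and 1393, as expression near 5 FPKM then counts for less. With log2(FPKM + 0.1) the first 3 were 1393, 41 and 495. By adjusted p alone they were 9479, 5432, 8251, 9956, 10321, 10198 and 10192, and with a log2 fold change of at least 2 they were 180, 6, 12, 627, 1098, 821 and 821, which follows from the minimum itself. Without small RNA genes the second comparison had 8. Leaving out each library in turn gave 881 to 890, 13 to 16, 301 to 313, 1990 to 2009, 3517 to 3530, 2567 to 2584 and 2528 to 2553.

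The ratio of the distances to naive of the IL-2 and the cocktail CD44loCD62L+ cells was 1.30, and was 1.26 with log2(FPKM + 0.1), 1.33 with log2(FPKM + 5) and 1.28 to 1.31 with each library left out. The number of changes against naive shared by the 4 cultured populations was 1448, and was 744 with log2(FPKM + 5), 7310 by adjusted p alone and 475 with a log2 fold change of at least 2. The number of list tests passing ran from 75 with an estimated correlation, against 94, to 103 without a filter. The ribosomal protein list in the cocktail CD44loCD62L+ against naive cells lost its call after quantile normalization (adjusted p = 0.652), where its mean stayed negative at -0.0403 while the direction of its test against the other genes turned. The median log2 fold change of all genes was then -0.0860, below the list mean, and the test compares the list with the other genes. Why quantile normalization moved these values was not tested. Quantile normalization also ended the call of that list in the other comparisons where it had passed, of the effector list between the cocktail CD62L+ and CD62L- cells and of the endoplasmic reticulum chaperone list in the cocktail CD44+CD62L+ against naive cells. The filter of 5 FPKM ended that of the B cell markers in 3 comparisons. All 96 pairs of a named gene and a comparison kept their calls in every alternative run on them, except 6 with log2(FPKM + 5): Penk, Ifitm1 and Klra5 between the cocktail CD62L+ and CD62L- cells, and Bambi-ps1, Ephx1 and Matk between the cocktail CD44loCD62L+ and CD44+CD62L+ cells.

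With the replicate number as a block the counts were 881, 13, 303, 1993, 3520, 2564 and 2532, the shared changes 1448 and the list tests passing 93. The numbers did not pair the libraries: over 8394 genes the deviations of same-numbered libraries correlated by -0.0343 on average (-0.461 to 0.403), and 4 of 30 pairs were above 0.1. Each comparison allows 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave the counts above, the highest in 1 of 10 splits in each comparison, and the highest of the other splits gave 0, 1, 0, 1, 1, 1 and 0 genes. Each other split mixed libraries of the populations compared, so their difference entered the residual spread and low counts were built in. The splits are therefore not evidence for the counts. Unknown depth leaves open how far low genes are limited by counting, and technical libraries cannot show variation between mice or cultures.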

Other observations

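The test of the order of the populations was chosen only after the result was seen.

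Chemokine, adhesion and homing genes moved in both directions against naive cells: 9 and 7 of 26 rose and fell in the cocktail CD44loCD62L+ cells and 12 and 9 of 26 in the IL-2 cells, with no shift of the list (adjusted p = 0.658 and adjusted p = 0.703). In the cocktail CD44loCD62L+ cells, the inflammatory chemokine receptor gene Ccr2 (89.9 ± 0.784 against 0.684 ± 0.0705 FPKM) was higher than in naive cells, and Itgae, an integrin gene of tissue-resident cells (0.412 ± 0.0653 against 39.0 ± 0.615 FPKM), and Ccr9 were lower. Cytokine receptor genes likewise went both ways, with 9 and 7 of 25 risen and fallen there. Il12rb2, the inducible IL-12 receptor chain, was at 54.6 ± 0.981 against 1.97 ± 0.0473 FPKM and Il6st, the signalling chain of the IL-6 receptor, at 11.2 ± 0.0667 against 71.1 ± 0.659 FPKM.

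Among apoptotic genes, 7 and 1 of 22 rose and fell in the cocktail CD44loCD62L+ against naive cells, without a shift of the list (adjusted p = 0.0659). Fasl, the Fas ligand gene, was at 29.3 ± 0.971 against 0.315 ± 0.0172 FPKM, while Bbc3, encoding the pro-apoptotic protein PUMA, was at 14.8 ± 0.230 against 39.5 ± 0.668 FPKM. Between the culture conditions, Fas was higher in the cocktail CD44+CD62L- than in the IL-2 cells, at 34.8 ± 1.23 against 1.93 ± 0.236 FPKM. Heat shock genes fell in 3 of 10 members against naive cells in the cocktail CD44loCD62L+ cells, with Hsph1 at 17.8 ± 0.286 against 118 ± 1.25 FPKM and Dnajb1 at 24.9 ± 0.305 against 101 ± 1.67 FPKM, again without a shift of the list (adjusted p = 0.186). Fatty acid oxidation genes were not shifted in any comparison. Acadl was at 144 ± 1.48 against 21.5 ± 0.688 FPKM and Lipa at 18.5 ± 0.225 against 55.6 ± 0.729 FPKM in the IL-2 against naive cells.

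The populations may form a graded series from the IL-2 cells through the cocktail CD44+CD62L-, CD44+CD62L+ and CD44loCD62L+ cells to naive cells. Of 4575 genes whose group means spanned at least 1 log2 unit, 1077 followed this order, 532 rising and 545 falling, the most of any of the 60 possible orders, for which the mean was 74.7. That mean is not a chance level, since the cocktail populations were closer to each other than to the IL-2 or naive cells. Steps of any size between neighbouring populations were counted. The order with the cocktail CD44+CD62L- and CD44+CD62L+ populations exchanged held 1026 genes, so the data barely separate these positions. Their distances to naive cells ran the other way, at 1.19 for the CD44+CD62L- and 1.20 for the CD44+CD62L+ cells, with overlapping ranges. The populations were defined by gates and the genes are not independent, so the count is a description of these libraries and does not show that cells pass through the series.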
